A study of Homo sapiens with 4 samples.

How the data were processed

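Gene expression was measured on Affymetrix Human Transcriptome Array 2.0 arrays in Y79 cells, a human retinoblastoma line that grows in suspension. Per the labels' protocols, cells were transfected and harvested after 48 h, total RNA was extracted with Trizol and treated with DNase, and biotin-labelled cDNA was hybridised. The 4 arrays formed 2 groups of 2: empty vector (arrays 1 and 2) and LOX-PP, the overexpressed propeptide of lysyl oxidase (arrays 1 and 2). The labels do not say whether arrays of a group came from separate cultures. The series design states that there were no technical replicates. If arrays of a group share a culture, the p-values measure only the spread between these arrays, which may be technical.

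The deposited values are log2 signals, 1 per transcript cluster and array. Per the labels, the authors summarised them with the robust multi-array average (RMA) in Expression Console, which corrects the background and normalizes between arrays. The series design names Transcriptome Analysis Console 4.0 as the processing software, so which program made the values is not settled by these sources. The genome build and the annotation version are not given in the sources used here, and no coordinates are printed. The 4 columns did not share one distribution. Medians over tested transcript clusters were 5.58 and 5.59 in the empty vector arrays and 5.70 and 5.65 in the LOX-PP arrays, and standard deviations over transcript clusters were 2.32, 2.36, 2.26 and 2.25 in the same order. The background control probe sets, which match no human sequence, had medians of 3.65 to 3.77 and single values of 2.71 to 7.61. The highest of these lay above the upper quartile of every array (7.25 to 7.33). A signal within that range is thus not shown to be absent. The number of arrays limits the precision of each value.

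The table held 70523 rows. Control rows, 2995 in number, stayed out of every test, which left 67528 transcript clusters. The platform annotation gave 1 gene symbol to 23781 of these and several symbols to 1543. The other 42204 are unnamed here. Older symbols were updated through a table of human genes of assembly GRCh38.p14, used for names only. Where a symbol had several transcript clusters, the one with the highest mean over all 4 arrays stood for it, which gave 22465 symbols. A total of 1687 transcript clusters repeated the 4 values of another.

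The LOX-PP arrays were compared with the empty vector arrays by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the sole term, no further normalization, no filter on low values), with two-sided tests and Benjamini-Hochberg adjustment over all 67528 transcript clusters. The fit had 2 residual degrees of freedom and a prior worth 2.71. The threshold was an adjusted p of 0.05. An exact permutation test of 2 arrays against 2 cannot go below p = 0.33 and was not used for calls. Differences are LOX-PP minus empty vector on the log2 scale.

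Before the data were examined, the design, the alternatives, 30 lists of genes that share a process and 10 lists of cell type markers were fixed, together with the rule for the genes named. The lists held 881 genes, of which 756 were measured and 125 were not matched. Lists with at least 5 measured genes, 38 in number, were tested with camera at a preset correlation of 0.01, with adjustment over the lists. Camera asks whether the genes of a list differ from all other genes. It was repeated with the correlation between genes estimated for each list. As another alternative, fry tests whether the genes of a list move, on balance, one way, without comparing them with other genes. Members were also adjusted over the list alone. Each list's median was set against 10000 random lists of the same size, matched on mean signal in 40 bins. These lists describe the arrays at hand and give no p-value.

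The rule named LOX first. It then took, in each direction, the 15 largest differences among genes with 1 symbol whose LOX-PP arrays both lay beyond both empty vector arrays and whose higher group mean exceeded the median of all tested values. Genes past the adjusted threshold went first, and places left went to genes with an unadjusted p under 0.05, which are given as values and not as changes. Uncharacterised, small nucleolar and microRNA transcripts were counted and not named in these places. From each list it took up to 3 genes with the smallest p in each direction. Pseudogenes and 5S ribosomal RNA copies are uncertain, since probes may read near-identical copies.

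The alternatives were a replicate block, quantile normalization, median centring, an intensity trend with a robust prior, a filter on low values (mean at least the median of all tested transcript clusters), array weights, leaving out each array, 1-symbol transcript clusters alone, an unmoderated linear model, an unadjusted p with a 2-fold difference, the mean of all transcript clusters of a symbol, and the set tests above. Cyclic loess between arrays and the removal of repeated transcript clusters were added after the data were seen.

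The statistics were tested on simulated data with known answers before use. For LOX-PP against empty vector, 67528 transcript clusters were simulated, some of them changed by a known amount. With spreads drawn from the fitted prior, the test recovered 0 of 64 at a log2 difference of 1, 55 of 72 (76.4%) at 2 and 59 of 64 (92.2%) at 3, with 7 unchanged transcript clusters called. With the same spread for every transcript cluster, 100% were called at each size. For the set test, 38 simulated lists of 25 genes among 22465 held 1 list shifted by -0.4. Camera called that list at the preset correlation and 0 of the others. With an estimated correlation its adjusted p in camera was 0.354, so it was not called. A missing call under that setting thus does not show that a shift is absent. The simulated genes were independent and had no shift with brightness, so the simulation does not show how the preset correlation behaves where genes correlate. On the arrays, the estimated correlation was 0.159 for mitosis genes, 0.14 for p53 targets and 0.215 for rod genes. Plots were drawn with matplotlib 3.10.9.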

Results

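Transcript levels were measured in Y79 retinoblastoma cells 48 h after transfection with an empty vector (2 arrays) or with a construct for LOX-PP (2 arrays). LOX-PP is the propeptide that is cut from the lysyl oxidase precursor when the enzyme matures. All pairs of arrays correlated closely over 67528 transcript clusters, which are not independent replicates. Pearson's r was 0.993 between the empty vector arrays, 0.989 between the LOX-PP arrays and 0.994 between empty vector array 2 and LOX-PP array 2, so the LOX-PP arrays were not the closest pair. Signals ran from 2.29 to 19.9 with a median of 5.63.

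The first comparison asked whether the transcript of LOX itself, the gene whose propeptide was overexpressed, differed between the groups. The LOX signal (transcript cluster TC05001714.hg.1) was 5.27 and 5.33 in the empty vector arrays and 5.63 and 5.76 in the LOX-PP arrays. The means were 5.30 ± 0.04 and 5.70 ± 0.09 (SD, n = 2 each). Both LOX-PP arrays lay above both empty vector arrays. The difference was 0.40 (SE 0.11, 95% confidence interval 0.11 to 0.70). It had an unadjusted p of 0.0179 in limma and did not pass adjustment over all transcript clusters (adjusted p = 0.593). Other members of the lysyl oxidase family gave differences of 0.22 for LOXL4, -0.11 for LOXL2, -0.21 for LOXL3 and -0.20 for LOXL1, none past the threshold. The sign of LOXL1 and LOXL2 turned without empty vector array 1 (0.04 each), and that of LOXL1 also without LOX-PP array 2 (0.28). The LOX signal lay near the median of the arrays and within the range of the background control probe sets (2.71 to 7.61), and its difference stood at percentile 94.2 among the 1000 transcript clusters closest in signal. The central 95% of those transcript clusters ran from -0.25 to 0.49. The gene-level value may also include probes outside the propeptide sequence. The LOX signal thus does not settle how strongly the construct was expressed.

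The next comparison asked which genes and processes differed between the LOX-PP and the empty vector arrays. Genes of mitosis were lower as a group in the LOX-PP arrays, with a median difference of -0.38 and 49 of 50 measured genes below 0 (camera adjusted p = 1.02e-16, and adjusted p = 0.56 with an estimated correlation). Target genes of the tumour suppressor p53 were higher as a group, with a median of 0.22 and 21 of 24 genes above 0 (camera adjusted p = 3.39e-05, and adjusted p = 0.56 with an estimated correlation). Rod photoreceptor genes were higher as a group, with a median of 0.17 and 17 of 18 genes above 0 (camera adjusted p = 0.00101, and adjusted p = 0.56 with an estimated correlation). Of single genes, CDKN1A, which encodes the cell cycle inhibitor p21, was 8.86 ± 0.17 with empty vector and 9.69 ± 0.13 with LOX-PP (SD, n = 2 each), a difference of 0.84 (SE 0.14). CDKN1A did not pass adjustment over all transcript clusters (limma adjusted p = 0.593).

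Among the mitosis genes, the smallest p-values belonged to CDCA8, a subunit of the chromosomal passenger complex, at -0.58 (SE 0.11), to the spindle motor KIF11 at -0.46 (SE 0.10) and to the centromeric histone CENPA at -0.50 (SE 0.11). Chosen after their values were seen, FOXM1, a transcription factor of G2 and M phase genes, was 0.73-fold, ECT2, which drives cytokinesis, 0.67-fold, and the spindle assembly factor TPX2 0.73-fold. In 43 of 50 mitosis genes both LOX-PP arrays lay below both empty vector arrays, and 22 had an unadjusted p under 0.05 in limma. Chance gives such a separation in one direction in 16.7% of genes, against 86% of mitosis genes and 54.6% of all symbols in the brightest of 5 equal groups. CDCA3 was the one mitosis gene above 0, at 0.20. The mitosis median was -0.23 under quantile normalization and -0.19 under cyclic loess, where the call held. As deposited, the median lay below the central 95% of brightness-matched random lists (-0.27 to -0.15). Without LOX-PP array 1 the median was -0.26 and lay inside that range (-0.27 to -0.15).

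Genes of E2F and DNA replication were also lower as a group, with a median of -0.20, 38 of 48 genes below 0 and 11 of them at an unadjusted p under 0.05. The origin recognition subunit ORC6 was at -0.46, the DNA polymerase subunit POLA1 at -0.39 and the replicative helicase subunit MCM6 at -0.43, whereas CCNE1, which encodes cyclin E1, was at 0.18. The list passed at the preset correlation (adjusted p = 3.13e-05) and not with an estimated correlation (adjusted p = 0.56). Its median lay inside the range of brightness-matched lists (-0.26 to -0.13), and the call ended under quantile normalization (median -0.07) and cyclic loess (-0.03). Without empty vector array 2 or without LOX-PP array 1 the E2F median was -0.30. Genes that drive or are gained in retinoblastoma had a median of -0.26, with 12 of 15 below 0 (adjusted p = 0.008, and 0.56 with an estimated correlation). Among them the p53 antagonist MDM4 was at -0.41, the ubiquitin ligase subunit SKP2 at -0.57 and the chromatin remodeller HELLS at -0.35. The median of these genes lay inside the matched range (-0.28 to 0.00), and the call ended under quantile normalization (median -0.12), cyclic loess (-0.09), the filter on low values (-0.29) and without LOX-PP array 1 (-0.15). The oncogene MYCN, chosen after its values were seen, at 13.3 ± 0.44 with empty vector and 12.9 ± 0.53 with LOX-PP (SD, n = 2 each), overlapped between the groups. E2F3, UHRF1 and KIF14 of this list also stand on the cell cycle lists. The list also holds the tumour suppressor gene RB1 and its relative RBL2 beside gained genes. Its median thus does not show a direction of driver activity.

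Among the p53 target genes, 7 of 24 had an unadjusted p under 0.05, all higher in the LOX-PP arrays. GDF15, a secreted stress cytokine, was 6.58 ± 0.36 with empty vector and 7.84 ± 0.40 with LOX-PP (SD, n = 2 each), a difference of 1.25. Its empty vector signals, 6.33 and 6.84, lay within the range of the background control probe sets (2.71 to 7.61), as did 1 of its LOX-PP signals (7.55). The kinase PLK2 was at 0.41, with its signals, 5.22 to 5.69, also within that range. CDKN1A is also on this list. The other 4 of the 7 were named after their values were seen. MDM2, the ubiquitin ligase that limits p53, differed by 0.73 (SE 0.24), or 0.45 without empty vector array 1. DDB2, a damage-recognition protein of nucleotide excision repair, differed by 0.66 (SE 0.23), or 0.39 without that array. The growth arrest gene GADD45A was at 0.59 (SE 0.16) and the translesion polymerase POLH at 0.29, while TIGAR, a regulator of glycolysis, was at -0.24. The p53 list median was 0.31 under quantile normalization, 0.34 under cyclic loess and 0.13 under median centring, with the call held in each. As deposited, the median of 0.22 lay above the central 95% of brightness-matched lists (-0.21 to -0.03).

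**Figure D1:**
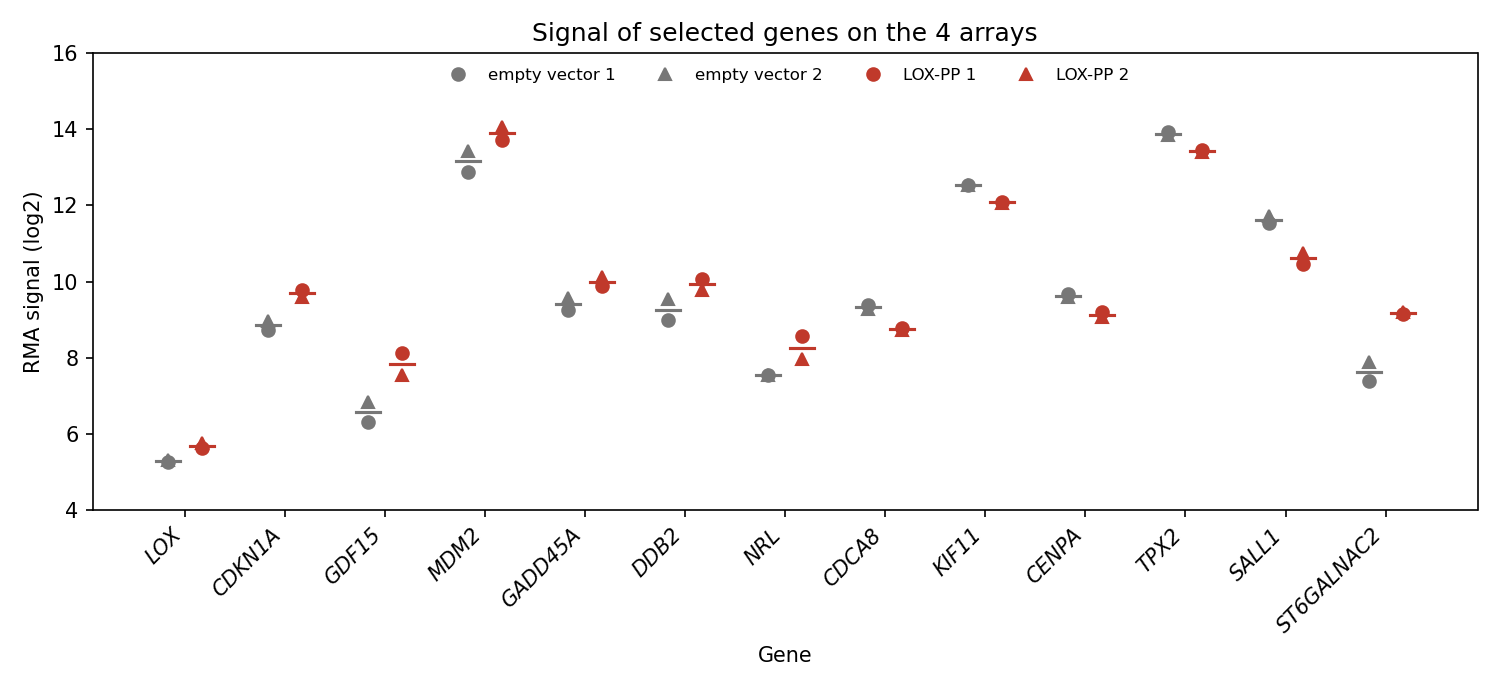
RMA signal (log2, vertical axis) of 13 genes on each array, with empty vector in grey, LOX-PP in red, circles for array 1, triangles for array 2 and a bar at each group mean. GDF15 lay at 6.58 with empty vector and 7.84 with LOX-PP on average, CDKN1A at 8.86 and 9.69, and CDCA8 at 9.33 and 8.75.

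NRL, the transcription factor that sets rod fate, was 7.55 and 7.56 in the empty vector arrays and 8.57 and 7.96 in the LOX-PP arrays, a difference of 0.71 (SE 0.23), or 0.40 without LOX-PP array 1. Both empty vector signals lay within the range of the background control probe sets over all arrays (2.71 to 7.61). They lay above the highest background control of their own arrays (6.72 and 7.50). Further rod genes included the phosphodiesterase subunit PDE6A at 0.33, the lipid transporter ABCA4 at 0.24 and, chosen after its value was seen, the disc rim protein PRPH2 at 0.33. GNB1 was the one rod gene below 0, at -0.12, but it stood at -0.02 without LOX-PP array 2, -0.23 without LOX-PP array 1 and -0.07 without empty vector array 1, and its sign turned under cyclic loess (0.08). In 11 of 18 rod genes both LOX-PP arrays lay above both empty vector arrays. The rod list median was 0.10 under quantile normalization, 0.11 under cyclic loess and 0.07 under median centring, with the call held in each. As deposited, the median of 0.17 lay above the central 95% of matched lists (-0.03 to 0.11). The mean signal over the rod list was 6.58. Cone photoreceptor genes did not pass (median -0.04, camera adjusted p = 0.401), with 8 of 20 genes above 0 and 12 below. Of those below 0, the homeobox gene OTX2 stood at -0.30. The cone transducin GNAT2 stood at -0.48, or -0.24 without empty vector array 1. The retinoid receptor RXRG stood at -0.46, or -0.73 without empty vector array 1 and -0.20 without empty vector array 2. The difference between the rod and cone lists was not tested.

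Several groups of bright genes were slightly lower in the LOX-PP arrays as deposited. Cytosolic ribosomal proteins had a median of -0.12 with 33 of 38 genes below 0 (adjusted p = 0.00247, and 0.613 with an estimated correlation), a sign that turned under quantile normalization and cyclic loess. RPS25 was at -0.33, RPS23 at -0.29 and RPL37 at -0.27. Nuclear-encoded genes of oxidative phosphorylation had a median of -0.13 with 28 of 34 below 0 (adjusted p = 0.00492, and 0.56 with an estimated correlation), which also turned under both of those normalizations. Its members with the smallest p were NDUFS3 at -0.45, NDUFS1 at -0.31 and NDUFA9 at -0.67 (-0.37 without LOX-PP array 1). MYC target genes of ribosome biogenesis and metabolism had a median of -0.16 with 25 of 29 below 0 (adjusted p = 0.00492, and 0.613 with an estimated correlation), and the sign turned under cyclic loess. The nucleolar protein gene NOP58 was at -0.48 and the transferrin receptor TFRC at -0.35. Anti-apoptotic regulators had a median of -0.18 with 11 of 13 below 0 (adjusted p = 0.0284, and 0.56 with an estimated correlation), with MCL1 at -0.36 (-0.22 without LOX-PP array 1), API5 at -0.50 (-0.24 without that array and -0.77 without LOX-PP array 2) and BIRC5, which is also a mitosis gene, at -0.31. The medians of all 4 of these lists except that of the ribosomal proteins lay inside their brightness-matched ranges, and the ribosomal median lay above its range (-0.28 to -0.15). Quantile normalization and cyclic loess ended all 4 calls with medians near 0 or turned, at -0.03 and 0.02 for MYC targets and -0.05 and -0.03 for the anti-apoptotic list. The filter on low values also ended all 4 but left the medians at -0.12, -0.13, -0.16 and -0.21 in the order above. Median centring ended that of the anti-apoptotic list, as did the trend with a robust prior and the replicate block (camera adjusted p = 0.0525). Under median centring the ribosomal median was -0.21, that of oxidative phosphorylation -0.23, that of MYC targets -0.26 and that of the anti-apoptotic list -0.27. Without LOX-PP array 1 the ribosomal median was -0.24 and that of MYC targets -0.25, and without empty vector array 2 they were -0.18 and -0.28. Without empty vector array 1 the median of MYC targets was -0.06. Without LOX-PP array 2 the ribosomal median was -0.01, and those of oxidative phosphorylation and MYC targets were both -0.03.

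Groups of signalling genes with low signal were slightly higher. Target genes of NF-kB had a median of 0.13 with 19 of 20 above 0 (adjusted p = 0.00492, and 0.56 with an estimated correlation), with the chemokine CCL2 at 0.38, IER3 at 0.32 and CXCL8 at 0.27. The signals of CCL2, IER3 and CXCL8 lay within the range of the background control probe sets (2.71 to 7.61). Angiogenesis factors had a median of 0.12 with 19 of 21 above 0 (adjusted p = 0.00517, and 0.56 with an estimated correlation), with the receptor gene TEK at 0.25, FGF1 at 0.26 and VEGFB at -0.21. Interferon-stimulated genes had a median of 0.08 with 31 of 38 above 0 (adjusted p = 0.0115, and 0.56 with an estimated correlation), a sign that turned under quantile normalization (-0.01), median centring (-0.01) and cyclic loess (-0.0046). The filter on low values left an interferon median of 0.01, and each of these settings ended the call. RSAD2, the interferon-stimulated gene with the smallest p, was at -0.47, or -0.28 without LOX-PP array 1. Quantile normalization and cyclic loess ended the NF-kB call (medians 0.03 and 0.04) and the angiogenesis call (0.03 and 0.03), and the filter on low values also ended the latter. Under median centring the NF-kB median was 0.04 and the angiogenesis median 0.03, with both calls held. The medians of the 3 lists lay inside their brightness-matched ranges. Without LOX-PP array 2 the calls of these 3 lists ended, as did those of the ribosomal, oxidative phosphorylation, MYC and anti-apoptotic lists.

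**Figure D2:**
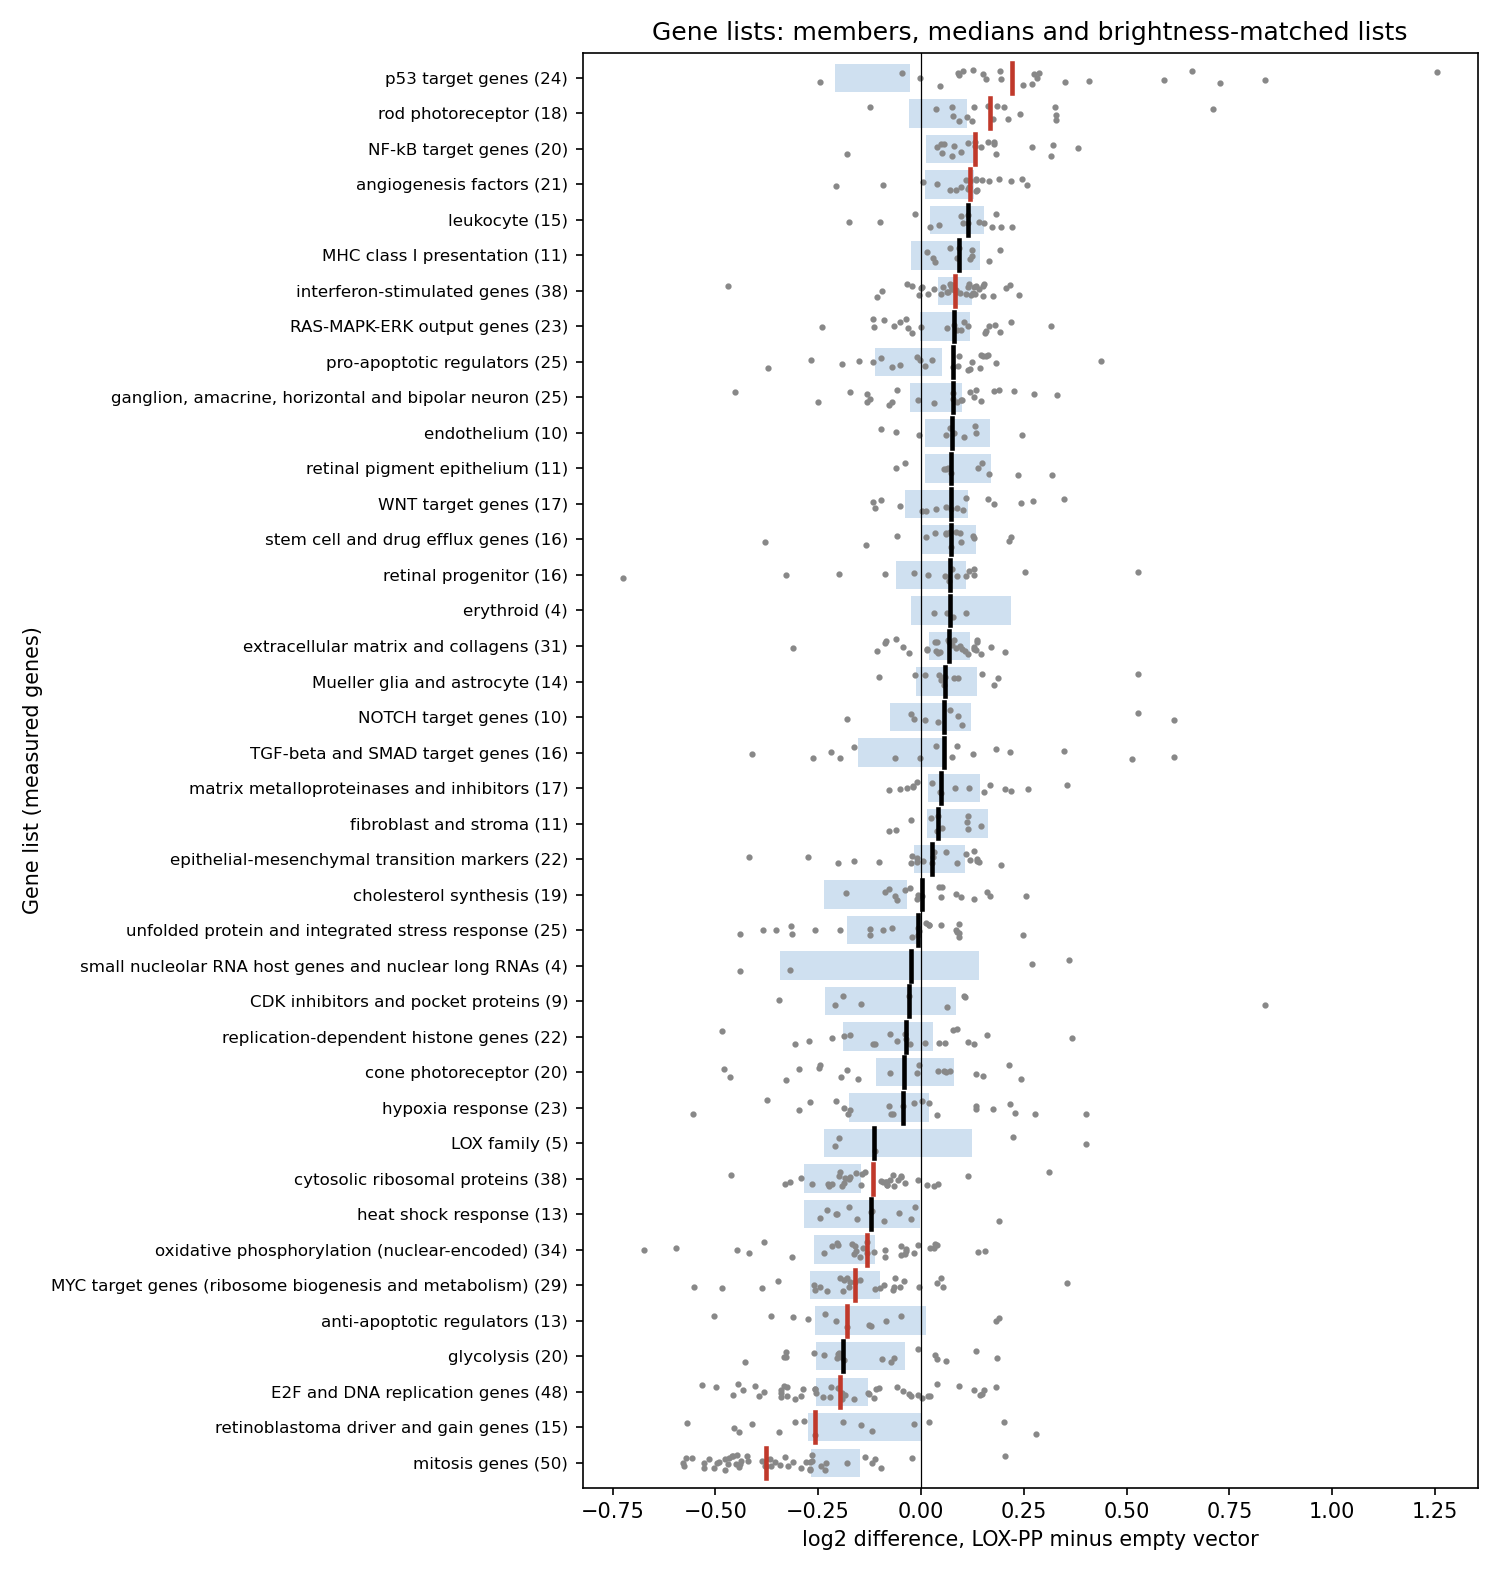
Log2 difference (LOX-PP minus empty vector, horizontal axis) of the measured genes of each list (dots, number in brackets), with the list median as a bar, red where camera at the preset correlation gave an adjusted p under 0.05, and a blue box for the central 95% of medians of brightness-matched random lists. The medians of mitosis genes (-0.38), p53 target genes (0.22) and rod genes (0.17) lay outside their boxes, as did those of ribosomal proteins, pro-apoptotic regulators and cholesterol synthesis.

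Of the 38 lists tested, 12 passed camera at the preset correlation, 5 higher and 7 lower in the LOX-PP arrays. With an estimated correlation 0 passed (smallest adjusted p = 0.56), and with fry 0 passed (smallest adjusted p = 0.167), with 0 and 6 lists respectively at an unadjusted p under 0.05. Without empty vector array 1 the MYC, interferon and anti-apoptotic calls ended, and without LOX-PP array 1 the retinoblastoma and anti-apoptotic calls. CDKN1A, on the list of CDK inhibitors and pocket proteins, was the sole member that passed limma when adjusted over the list alone (adjusted p = 0.0206), and 0 members of any list passed over all genes tested. Adjusted over the list alone, the smallest p was 0.0924 among mitosis genes and 0.0548 among p53 target genes. The CDK inhibitor list itself did not pass (median -0.03, mean 0.02, test direction down, adjusted p = 0.986), and the LOX family did not pass (median -0.11, mean 0.02, test direction up, adjusted p = 0.564).

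The other process lists did not pass as deposited. Medians were 0.08 for RAS-MAPK-ERK output genes (adjusted p = 0.281), 0.08 for pro-apoptotic regulators (0.525), -0.04 for replication-dependent histone genes (0.525), -0.19 for glycolysis (0.101), -0.04 for the hypoxia response (0.914) and 0.00 for cholesterol synthesis (0.584). The unfolded protein and integrated stress response stood at -0.01 (adjusted p = 0.306), the heat shock response at -0.12 (0.12) and MHC class I presentation at 0.09 (0.0521), with 11 of 11 genes above 0. Matrix genes and collagens had a median of 0.07 (adjusted p = 0.0854), metalloproteinases and their inhibitors 0.05 (0.101) and markers of epithelial-mesenchymal transition 0.03 (0.571, with a mean of -0.0010). WNT target genes stood at 0.07 (adjusted p = 0.17), NOTCH target genes at 0.06 (0.22), TGF-beta and SMAD target genes at 0.06 (0.568) and stem cell and drug efflux genes at 0.07 (0.12). Host genes of small nucleolar RNAs and nuclear long RNAs had 4 measured genes, too few for the test, and a median of -0.02. Markers of other cell types did not pass either. Retinal progenitor genes had a median of 0.07 (adjusted p = 0.306), Mueller glia and astrocyte genes 0.06 (0.0953), inner retinal neuron genes 0.08 (0.306), pigment epithelium genes 0.07 (0.0854), fibroblast and stroma genes 0.04 (0.401), endothelial genes 0.07 (0.19) and leukocyte genes 0.11 (0.0953). Of the tested lists that did not pass, the median turned sign in 17 under median centring, 10 under quantile normalization and 12 under cyclic loess. Single settings gave calls to a few of these lists. Glycolysis passed camera with the replicate block (median -0.19, adjusted p = 0.0145). Its median was -0.29 without empty vector array 2 and -0.33 without LOX-PP array 1, but -0.05 without empty vector array 1 and 0.05 without LOX-PP array 2. Cholesterol synthesis passed under quantile normalization (0.12, adjusted p = 0.00131) and cyclic loess (0.15, 0.000518). MHC class I presentation passed with the filter on low values (0.09, adjusted p = 0.0377), leukocyte genes without empty vector array 2 (0.17, 0.0291) and histone genes without LOX-PP array 1 (-0.33, 0.00257). The leukocyte median was 0.06 without empty vector array 1 and 0.05 without LOX-PP array 1, and the histone median was 0.13 without LOX-PP array 2. The median of cholesterol synthesis was -0.09 under median centring, -0.05 without empty vector array 2 and -0.02 without LOX-PP array 1. Erythroid genes, with 4 measured and so not tested, had a median of 0.07.

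Over all 67528 transcript clusters, 0 were higher and 0 lower at an adjusted p of 0.05 by limma (smallest adjusted p = 0.593), and the unmoderated linear model also gave 0. At an unadjusted p under 0.05 there were 5676, with 3090 higher and 2586 lower, where chance alone gives 3376. With each array centred on its median the split was 1329 higher and 5151 lower. A total of 82 transcript clusters combined an unadjusted p under 0.05 with a 2-fold difference (45 higher, 37 lower), of which 70 were unnamed and 4 were protein-coding genes. The groups did not overlap in 42.8% of transcript clusters, where chance gives 33.3%. The difference followed brightness, with a median of 0.10 in the dimmest of 5 equal groups of transcript clusters and -0.16 in the brightest.

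The genes named by size did not pass adjustment and are given as values. The largest positive difference of a protein-coding gene was that of the sialyltransferase ST6GALNAC2, at 7.64 ± 0.36 with empty vector and 9.18 ± 0.04 with LOX-PP (SD, n = 2 each), a difference of 1.54. Its signal in empty vector array 1, 7.39, lay within the range of the background control probe sets over all arrays. It lay above the highest background control of that array (6.72). The largest negative differences of protein-coding genes were those of the olfactory receptor OR2B6, at -1.21 (SE 0.42) but -0.61 without LOX-PP array 1, and of the zinc finger transcription factor SALL1, at 11.6 ± 0.13 and 10.6 ± 0.19 (SD, n = 2 each), or 0.49-fold. STOX2 stood at 0.82, the potassium channel gene KCNB2 at -0.81 and ECH1, an enzyme of fatty acid oxidation, at -0.75. Non-coding transcripts held most of the other places. Those above 0 were RNA5SP162 (2.53), SGO1-AS1 (2.02), the minor spliceosome RNA RNU11 (1.46), RNU6-67P (0.99), RNU7-51P (0.96), RNA5SP308 (0.82), RNA5SP238 (0.79) and GAS6-DT (0.77), and the antigen receptor segments IGHD3-22 (1.11), IGHJ1 (0.96) and TRAJ14 (0.87). Those below 0 were RNA5SP268 (-1.06), RNA5SP82 (-0.997), RNA5SP348 (-0.83), RNU7-77P (-0.79), TCF7L1-IT1 (-0.76), E2F3-IT1 (-0.75) and the pseudogenes COX11P1 (-0.90), ZNF66P (-0.82), PSAT1P4 (-0.81), HNRNPA3P5 (-0.78) and RAC1P2 (-0.75). All of these had an adjusted p of 0.593 in limma. Several of these values rested on 1 array. Without LOX-PP array 1, RNU6-67P stood at 0.64, RNA5SP308 at 0.40, RNA5SP238 at 0.40, RNA5SP268 at -0.60, COX11P1 at -0.54, ZNF66P at -0.47 and HNRNPA3P5 at -0.51. Without LOX-PP array 2, RNA5SP308 stood at 1.23. Without empty vector array 1, RNU11 stood at 0.75 and IGHD3-22 at 0.57, and without empty vector array 2, RNA5SP348 stood at -0.49.

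Several classes of small RNA set LOX-PP array 1 apart from the other arrays, but microRNAs did so little (41.4% of 1040 highest there). Antigen receptor D and J segments, which are not small RNAs, were also highest there (18 of 22, 81.8%). Of 239 small nucleolar RNAs, 162 (67.8%) had their highest signal there, as did 336 of 493 copies of 5S ribosomal RNA (68.2%), 21 of 23 small nuclear RNAs (91.3%) and 17 of 21 Cajal body RNAs (81%), against 37% of protein-coding genes. The median deviation of small nucleolar RNAs from the median of the other arrays was 0.48 in LOX-PP array 1 and -0.27 in LOX-PP array 2. In empty vector arrays 1 and 2 it was 0.03 and -0.16. Cajal body RNAs stood at 0.78 and -0.44 in LOX-PP arrays 1 and 2, and at 0.21 and -0.22 with empty vector. For both classes array 1 thus stood above array 2 in each group. With empty vector, small nuclear RNAs (-0.11 and 0.01) and 5S copies (-0.07 and -0.06) did not show that order.

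**Figure D3:**
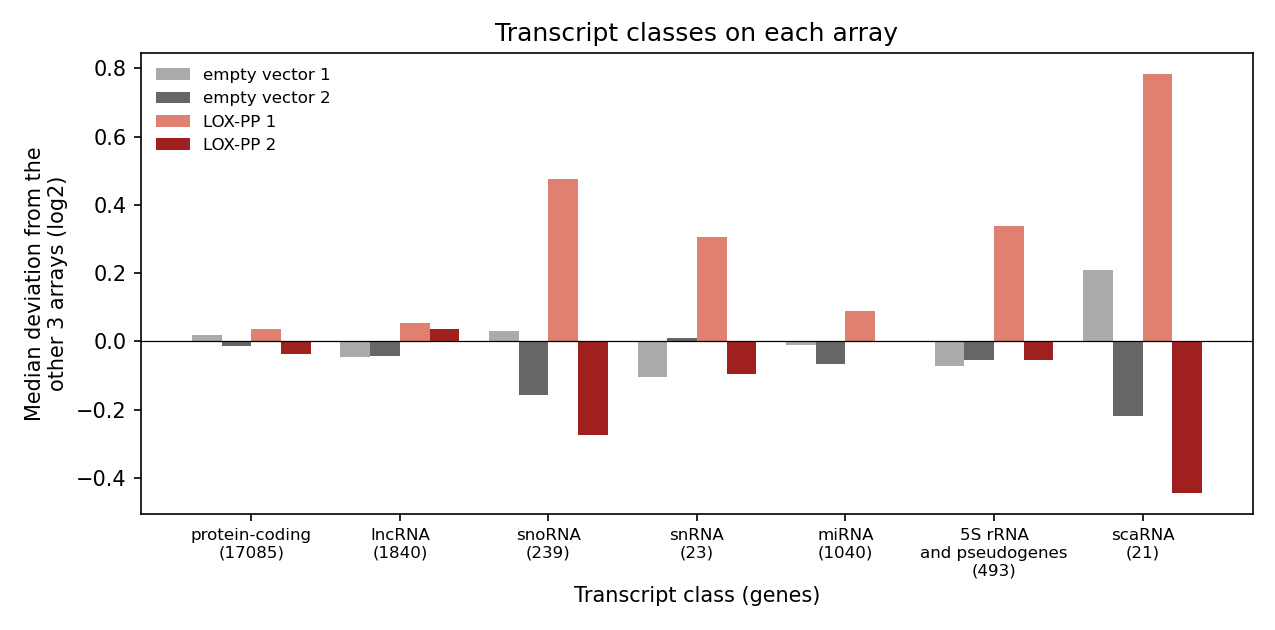
Median deviation of each transcript class from the median of the other 3 arrays (log2, vertical axis), with 1 bar per array and the number of genes in brackets. Small nucleolar RNAs stood at 0.48 in LOX-PP array 1 and -0.27 in LOX-PP array 2.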

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

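Of the settings in this part, cyclic loess and the removal of repeated transcript clusters were chosen after the data were seen. The count of transcript clusters past the threshold was 0 in every setting except an unadjusted p with a 2-fold difference, which gave 82, and it was also 0 in the replicate block and in each fit without 1 array (0 to 0). Without 1 array the 2-fold count was 158 without empty vector array 1, 213 without empty vector array 2, 197 without LOX-PP array 1 and 628 without LOX-PP array 2. At an unadjusted p under 0.05 quantile normalization left 3577, cyclic loess 3698 and the filter on low values 2705 of 33617 tested, and the fits without 1 array left 2805 to 8266, against 5676. LOX kept its sign in 10 alternatives, with differences of 0.30 to 0.47, adjusted p of 0.437 to 0.934 and 0.33 to 0.47 without 1 array. LOX had no value with the filter on low values, which removed it. The number of gene lists past the threshold, 12, became 0 with an estimated correlation, 0 with fry, 4 with quantile normalization (3 of the 12 and cholesterol synthesis), 6 with the filter on low values (5 of the 12 and MHC class I presentation), 4 with cyclic loess (3 of the 12 and cholesterol synthesis), and 5 to 14 without 1 array, 5 without LOX-PP array 2 (all among the 12). The cause was not tested. Among the 12 lists, signs of medians turned under quantile normalization for ribosomal proteins (0.0093), oxidative phosphorylation (0.0014) and interferon-stimulated genes (-0.011), under median centring for interferon-stimulated genes (-0.013), and under cyclic loess for ribosomal proteins (0.0656), oxidative phosphorylation (0.0381), MYC target genes (0.0182) and interferon-stimulated genes (-0.0046). The calls for mitosis, p53 target and rod genes held in 12 of 14 alternatives each, lost with an estimated correlation and with fry. The E2F list held in 10, NF-kB in 9, angiogenesis, retinoblastoma, ribosomal and oxidative phosphorylation genes in 8, MYC targets in 7, interferon-stimulated genes in 6 and anti-apoptotic regulators in 3. Single genes whose sign turned were GNB1 under cyclic loess (0.0846), LOXL1 (-0.679 to 0.282 without 1 array), LOXL2 (-0.262 to 0.0358) and RBP3 (-0.505 to 1.59). Besides the genes named by size, leaving out 1 array also moved by over 1.5 times the values of ADM, API5, BIRC5, BNIP3L, CASP6, CCNE1, DDB2, GNAT2, GNB1, HES1, HK2, ID1, ID2, ID3, KIF14, LOXL3, MCL1, MDM2, MYCN, NDUFA9, NRL, PDE6A, PMAIP1, PRPH2, RSAD2, RXRG, SEL1L, SFRP2, TIGAR, TRBJ2-2P, UHRF1, VEGFB and XBP1, which did not pass and are given as values. With the replicate block, LOX differed by 0.40 (adjusted p = 0.451), 12 lists passed (11 of the 12, with glycolysis, adjusted p = 0.0145, in place of the anti-apoptotic list, 0.0525) and 7469 transcript clusters had an unadjusted p under 0.05. Over all transcript clusters, the array 1 minus array 2 differences of the 2 groups had a correlation of 0.227. With 2 arrays per group this does not settle whether same-numbered arrays belong together.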

Other observations

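Tests chosen only after the result was seen were those of list medians against brightness-matched lists over all 4 arrays, the replication list as a reading of the cell cycle, small nucleolar RNAs in LOX-PP array 2 and the splits of the 2-fold count.

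Single genes of lists that did not pass are given as values. HES1, a target of NOTCH signalling, was 5.26 ± 0.10 with empty vector and 5.79 ± 0.26 with LOX-PP (SD, n = 2 each). Both HES1 means lay within the range of the background control probe sets (2.71 to 7.61). Of the TGF-beta and SMAD target genes, ID3 stood at 0.61 (SE 0.21), ID2 at 0.51 and ID1 at -0.41. Among retinal progenitor genes, the secreted WNT antagonist SFRP2 was at 14.5 ± 0.50 and 13.8 ± 0.06 (SD, n = 2 each), a difference of -0.72. The adjusted p of each in limma was 0.593.

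Metabolic and stress genes outside the lists that passed gave values of both signs. The oxygen sensor EGLN1 was at -0.56 and BNIP3L at -0.37, while BNIP3 was at 0.22 and ADM at 0.23. PGAM1 stood at -0.33 and HK2 at -0.43 among glycolysis genes, and SEL1L at -0.44 and XBP1 at -0.38 among unfolded protein response genes. Among apoptosis genes the p53-inducible PMAIP1 was at 0.44, with overlapping groups, and CASP6 at -0.37. Genes named by their zinc fingers (533) had a median difference of -0.14 and a median deviation of -0.18 in LOX-PP array 1. RBP3, a photoreceptor matrix protein chosen after its values were seen, read 10.6 and 9.32 in the empty vector arrays and 11.6 and 9.45 in the LOX-PP arrays, and TRBJ2-2P, chosen likewise, read 15.5 in LOX-PP array 2 against 11.5 to 11.9 elsewhere.

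Lower mitosis genes may reflect a shift between groups that depends on brightness, a single array or fewer dividing cells. The list median lay below all brightness-matched lists (percentile 0 of 10000) over the 4 arrays. It also stood at percentile 0 without empty vector array 1, without empty vector array 2 and without LOX-PP array 2. Without LOX-PP array 1 it stood at percentile 4.92, inside their central 95% (-0.26 against -0.27 to -0.15). Brightness thus stays open, and the part beyond it may rest on LOX-PP array 1. If fewer cells were in cycle as a whole, replication genes would be low too, but the E2F list stood at percentile 45.05 of its matched lists and, without 1 array, at 0.1 to 80.23, so this and a brightness shift of the E2F list cannot be told apart from the alternatives on these arrays. The 4 arrays allow 3 splits, too few for a share under 0.05: the mitosis median lay 0.17 from its matched median in the real split (1 of 3 as large) and at most 0.10 in the others, and 12 lists passed in the real split (1 of 3) against at most 5. The 2-fold count was 82 in the real split and 245 when arrays were parted by number (2 of 3 as large). The count at an unadjusted p under 0.05 in limma was largest in the real split, at 5676, against 4357 by number and 1451 in the other split. A structure of the arrays other than the groups is thus possible and was not tested. Mitosis genes passed camera in both other splits as well (adjusted p = 0.0393 and 0.00439).

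The higher medians of p53 target and rod genes stood at percentiles 100 and 99.95 of matched lists. In every fit without 1 array they stood at 99.36 or above. Brightness alone thus did not reproduce them, but these percentiles cannot exclude chance. Matched lists ignore the correlation between genes of a list, estimated at 0.14 for p53 targets and 0.215 for rod genes. Parted by number, the mitosis list stood at percentile 99.31 and the p53 list at 96.62, and in the other split the mitosis list stood at 0.02. Without LOX-PP array 1 the p53 list stood at percentile 100, which argues against that array as its source. In the other splits neither list passed camera (adjusted p = 0.0594 and 0.977 for p53 targets, 0.796 and 0.977 for rod genes). Transfection dose, culture differences between arrays and an effect of the construct stay open, and neither an estimated correlation nor fry gave a call. The estimated correlation also missed a simulated list with a known shift (camera adjusted p = 0.354), so it cannot decide here. Fry was not simulated. By contrast, interferon-stimulated genes stood at percentile 48.19, where the brightness shift could account for their median, and the LOX difference stood at percentile 94.2 of transcript clusters of like signal.

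The high small nucleolar RNAs of LOX-PP array 1 could reflect the construct, the brightness of the array or its RNA preparation. The construct would raise them in both LOX-PP arrays, but their median deviation in LOX-PP array 2 was -0.273 (95% interval -0.34 to -0.21). That interval covers the spread over small nucleolar RNAs within 1 array and not the spread between arrays. The deviation is taken from a median that includes the high LOX-PP array 1, which can lower it. Brightness would move protein-coding genes of the same signal alike, but the median deviation in LOX-PP array 1, 0.48, stood at percentile 100 of matched protein-coding lists (-0.05 to 0.02). Small RNA carried through the extraction or labelling of that array is a candidate source that was not tested. Small nucleolar RNAs also stood higher in array 1 than in array 2 with empty vector (0.03 and -0.16). A difference by array number was not tested for them. MicroRNAs deviated by 0.09 there, and antigen receptor D and J segments, which are not small RNAs, by 0.53.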
